A study of Mus musculus with 3 samples.

How the data were processed

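The samples were 2 H2AK119ub ChIP-seq libraries and 1 input library from EpCAM-sorted tongue epithelium of control mice at postnatal day 0. Libraries were made from 4 ng of DNA, per the labels' protocols. Processed lists were analysed for both H2AK119ub replicates, and the input library was not analysed here. The 2 replicates formed 1 group, so no treated or mutant group was compared.

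The authors deposited 1 list of called regions per replicate, so regions were called per sample and not on pooled reads. Each list gives a chromosome, a first and last coordinate in mm10, 1 of 4 location classes (promoter, gene body, distal or intergenic) and, outside the intergenic class, 1 or more gene names, per the file headers. Bowtie2 2.3.3 and SAMtools 0.1.19 are named per the submitters' processing notes, with no role stated. The peak caller, its settings, the use of the input, the coordinate base and the distances that define the location classes are not given in the sources used here. The lists hold no height, score, fold or p-value, so regions could not be ranked by strength and the depth of the libraries is unknown. No gap between neighbouring regions was under 999 bp, so stretches of signal closer than that may stand as 1 region, which affects widths and counts. Of the gene names given to promoter regions and matched to the reference, 92.4% in replicate 1 and 92.9% in replicate 2 had an end of the gene within 2 kb.

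Gene positions and biotypes came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 also names. It has 21631 protein-coding genes on the autosomes and X. Names in the lists were matched by symbol and then by a synonym held by 1 gene only. In promoter regions, 11 of 3392 assignments in replicate 1 and 10 of 3276 in replicate 2 had no match. The table gives gene bounds without strand, so a transcription start could not be told from a gene's other end, and no genome sequence was used.

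Overlap was counted from 1 bp. For chance overlap, the regions of a list were placed at random on their own chromosome within the gene-bearing span, with widths kept, 1000 times (100 times for the overlap of at least 50% of both regions). Differences in median width were tested by two-sided permutation with 100000 resamples. A gene was marked when a promoter region named it in both replicates. Each of 22 gene lists was tested against the other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 22 lists. Of the listed names, 3 had no entry in the reference (Calhm3, Skn1a and Loricrin) and were left out. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Mean ± SD is over the 2 replicates. On simulated lists of 20 genes, judged by the unadjusted p at a background of 8.7%, 98% of lists raised to an expected 45.2% marked were recovered, 50% of lists raised to 22.4%, and 2.5% of unchanged lists were called. The simulation marked each gene independently, so these rates do not cover lists whose neighbouring genes share regions.

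The lists, tests, alternatives and rules for naming genes were fixed before the data were examined, and the content of the files required departures from them. A distance to the transcription start had been planned for marked genes, with starts from the reference as the substitute. Neither could be had, so the promoter class of the authors was used, and regions within 1000, 5000 or 50000 bp of either gene end served as alternatives. Region width took the place of the planned score in ranking, in the stricter threshold (regions above the median width of each list) and in the comparison of shared and unshared regions. Genes named in the text were a fixed set of 13 genes, the 12 shared regions with the highest mean of the 2 within-list width percentiles (that of the widest region of each list where several merged) and up to 4 marked genes per list with the widest regions, with all marked genes of the basal keratinocyte and housekeeping lists. Other genes named here were chosen after their values were seen, and some genes that the rule selects are not reported here. The alternatives also comprised leaving out each replicate, counting genes in either replicate, counting neighbouring genes as 1, leaving out genes held by more than 1 list, leaving out X and leaving out the widest 5% of regions. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.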

Results

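Chromatin immunoprecipitation and sequencing (ChIP-seq) of ubiquitinated histone H2A (H2AK119ub) was carried out on the tongue epithelium of newborn control mice at postnatal day 0. H2AK119ub is the mark that Polycomb repressive complex 1 (PRC1) deposits, and the series asks about the role of that complex in the development of this epithelium. Cells carrying the epithelial surface protein EpCAM were sorted from tongues from which the circumvallate papillae, the large posterior taste papillae, had been cut away. There were 3 libraries, namely 2 H2AK119ub replicates, described by the submitters as biological, and 1 input library, which was not analysed here. Each replicate had its own list of called regions in mm10 coordinates. The lists hold no read counts or heights, so the depth behind a region is unknown and the values below describe presence and width.

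The first comparison asked how far the regions of the 2 replicates coincided. The 12 shared regions that ranked highest in width, by the mean of their width percentiles in the 2 lists, included 1 at each of the Hox clusters, which hold the transcription factor genes that pattern the body axis, and regions over the developmental transcription factor genes Pax3, Zic1 with Zic4 and Tbx1. Of these 12, 6 held a gene of the developmental regulator lists, while others lay over an intergenic stretch and an array of ribosomal RNA genes. Replicate 1 had 7838 regions with a median width of 4864 bp that covered 60.1 Mb. Replicate 2 had 8093 regions with a median width of 4219 bp that covered 52.8 Mb. Of the replicate 1 regions, 4788 (61.1%, exact 95% binomial interval 60.0 to 62.2%) overlapped a replicate 2 region by at least 1 bp. Of the replicate 2 regions, 4949 (61.2%, 60.1 to 62.2%) overlapped a replicate 1 region. Random placement on the same chromosome gave 4.67% and 4.63%, so that overlap was 13.1-fold and 13.2-fold above random (one-sided permutation test, p = 0.001 in each list, the smallest that 1000 placements can give). When each region had to cover at least 50% of the other, 35.4% and 34.3% were shared. In base pairs, the lists shared 32.5 Mb of the 80.4 Mb that either covered. These intervals cover counting error only, and regions of a list are not biological replicates.

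These 12 regions were named by a fixed rule. The Hoxa region on chromosome 6 ran from 52141365 to 52333041 in replicate 1 and from 52143182 to 52300442 in replicate 2, widths of 192 and 157 kb. The Hoxc region on chromosome 15 (102887225 to 103071523 in replicate 1) was 184 and 179 kb wide, the Hoxb region on chromosome 11 (96246587 to 96382767) 136 and 131 kb, and the Hoxd region on chromosome 2 (74641419 to 74758479) 117 and 127 kb. Pax3 on chromosome 1 lay in regions of 74.5 and 68.1 kb, Zic1 with Zic4 on chromosome 9 in regions of 68.1 and 67.6 kb, Tbx1 on chromosome 16 in regions of 62.5 and 59.6 kb, and Gse1 on chromosome 8 in regions of 57.9 and 87.8 kb. On chromosome 5 lay regions of 81.4 and 53.5 kb, of which that of replicate 1 ended 44.2 kb from Rbpj, the transcription factor gene of Notch signalling. On chromosome 2 lay regions of 87.9 and 57.0 kb, of which that of replicate 1 carried the name of the gene Gm11468. An intergenic region on chromosome 6 between Hrh1 and Atg7 (114490192 to 114637521) spanned 147 kb in replicate 1 and 148 kb in replicate 2. A region on chromosome 8 (123524090 to 123627328) spanned 103 and 98.1 kb over 48 annotated ribosomal RNA genes.

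Regions found in a single replicate were narrower than shared regions. In replicate 1 the median width was 3152 bp for the 3050 regions without a partner and 6585 bp for the shared ones. In replicate 2 it was 2913 bp for the 3144 regions without a partner and 5471 bp for the shared ones (two-sided permutation tests, p = 1e-05 in each list, the smallest that 100000 resamples can give). Not every unshared region was narrow: the basal keratin gene Krt5 had a promoter region of 14.9 kb in replicate 2, wider than the median shared region, and none in replicate 1.

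The second comparison asked where the regions lay relative to genes, using the location class the authors gave each region. Promoter regions made up 33.4% ± 1.45 (SD, n = 2) of a list, gene body regions 28.2% ± 1.07, distal regions 22.5% ± 0.21 and intergenic regions 15.8% ± 0.17. Promoter regions were the widest class, with medians of 8080 bp in replicate 1 and 6843 bp in replicate 2, and they held 50.5% and 48.7% of the covered length. They were also the class most often shared, at 73.7% and 73.4%, against 52.7% and 53.4% of gene body regions. Of all regions, 36.7% in replicate 1 and 35.4% in replicate 2 lay within 2 kb of an end of a protein-coding gene, against 14.1% and 13.2% after random placement (one-sided permutation test, p = 0.001 in each list, the smallest that 1000 placements can give). Among shared regions the promoter class rose to 40.2%, and among regions above the median width it was 47.0%.

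**Figure D1:**
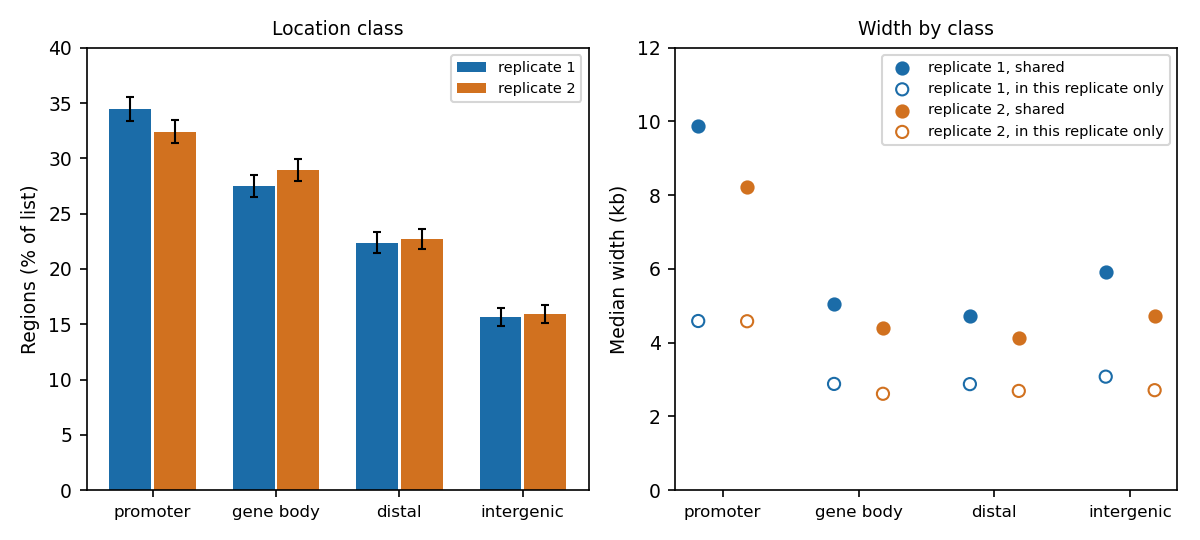
The left panel plots the percentage of regions in each location class for both replicates, with exact 95% binomial intervals as error bars, and the right panel the median width in kb of shared regions (filled) and of regions found in that replicate only (open). Promoter regions are the largest class in both lists, and shared regions are wider than unshared ones in every class.

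The third comparison asked which genes carried the mark. A gene was counted as marked when the authors' annotation named it for a promoter region in both replicates. Replicate 1 named 2770 protein-coding genes and replicate 2 named 2690, and 1908 of the 21631 protein-coding genes (8.82%) were named by both, 5.54 times the 344 expected if the lists were independent. Of 22 gene lists fixed before the data were examined, 11 held more marked genes than the other protein-coding genes did, 1 held fewer and 10 did not pass the threshold (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted p under 0.05 over the 22 lists). Genes of a cluster share regions, so genes are not independent observations.

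Developmental transcription factor lists had the highest shares of marked genes. All 39 Hox genes were marked in both replicates (adjusted exact p = 3.8e-41 by Fisher's exact test), through 6 promoter regions in replicate 1 and 5 in replicate 2. With Hox genes within 100 kb counted as 1, 4 of 4 were marked (adjusted exact p = 0.000248). Of 110 other homeobox genes, 93 were marked (84.5%, exact 95% interval 76.4 to 90.7%, adjusted exact p = 2.1e-79). The widest of their promoter regions included those of Evx2, which shares the Hoxd region, of Pax3, of the muscle progenitor gene Pax7 (61.4 and 58.3 kb) and of Dlx5 (48.5 and 47.4 kb). Of 76 T-box, GATA, Sox and Fox genes, 44 were marked (57.9%, adjusted exact p = 2.2e-26), with Gata4 in regions of 46.7 and 48.1 kb, Sox1 in regions of 38.5 and 35.0 kb and Tbx2 in regions of 43.6 and 31.8 kb. Of 44 bHLH genes, 22 were marked (50%, adjusted exact p = 7.7e-12), including the heart and limb factor Hand2 (56.6 and 56.7 kb) and the neurogenic factors Neurod2 (53.0 and 44.6 kb), Neurog2 (28.7 and 26.5 kb) and Neurog1 (28.7 and 24.1 kb). The 4 lists together had 198 of 269 genes marked (73.6%), against 8.0% of the remaining protein-coding genes. Their promoter regions had a median width of 22951 bp against 7526 bp for other promoter regions in replicate 1, and of 21909 bp against 6454 bp in replicate 2 (two-sided permutation tests, p = 1e-05 each, the smallest that 100000 resamples can give).

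Lists of secreted signals also held more marked genes than the other protein-coding genes did. Of 19 Wnt ligand genes, 8 were marked (42.1%, adjusted exact p = 0.000309 by Fisher's exact test). Among them were Wnt6 and Wnt10a in a common region of 28.9 and 43.4 kb, Wnt11 (28.2 and 24.4 kb) and Wnt3. With Wnt genes within 100 kb counted as 1, 5 of 15 were marked (33.3%, adjusted exact p = 0.0183). Of 34 Bmp and Tgf-beta ligands and antagonists, 10 were marked (29.4%, adjusted exact p = 0.00124), including Inhbb (21.8 and 17.5 kb), Bmp7 (14.8 and 15.8 kb), Gdf6 (21.9 and 10.8 kb) and the Bmp antagonist Chrd (15.8 and 13.4 kb). Of 22 Fgf ligand genes, 6 were marked (27.3%, adjusted exact p = 0.0203), including Fgf8 (18.9 and 20.5 kb), Fgf9 (14.1 and 14.2 kb), Fgf11 (11.5 and 11.9 kb) and Fgf4 (10.9 and 12.2 kb). With genes of a list within 100 kb counted as 1, the Fgf list was at 21.1% (adjusted exact p = 0.118).

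In the Hedgehog list, Shh, the ligand that papillae and taste buds express, was marked in both replicates, by a region on chromosome 5 from 28454526 to 28473667 (19.1 kb) in replicate 1 and from 28454264 to 28481219 (27.0 kb) in replicate 2, over the gene itself (28456840 to 28467101). The transcription factor gene Gli2 (13.4 and 13.4 kb), Scube2, which aids release of the ligand (11.2 and 10.6 kb), and the ciliary gene Kif7 (4.63 and 5.12 kb) were also marked. In all, 4 of 18 genes were marked (22.2%, interval 6.41 to 47.6%), and the list did not pass the threshold (adjusted exact p = 0.107). Replicate 2 alone named 8 of the 18 (44.4%, adjusted exact p = 0.00171), adding among others Ihh and Dhh, while replicate 1 alone named 5 (27.8%, adjusted exact p = 0.103), so the list would pass without replicate 1. The receptor gene Ptch1 had no region over it in either list, the nearest lying 61.8 and 54.8 kb away. No region carried the name of Gli1, a target gene of the pathway, but promoter regions named for Arhgap9 (12.5 and 13.0 kb) reached into it in both replicates.

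Of the 32 taste bud genes that matched the reference, 4 were marked (12.5%, interval 3.51 to 29.0%, adjusted exact p = 0.577), among them Shh, Sox2, a progenitor factor of taste buds (6.42 and 2.93 kb), and Car4 (4.35 and 4.02 kb). Of the others, 10 were named in 1 replicate only, and replicate 2 alone gave 10 of 32 (31.3%, adjusted exact p = 0.00709). Prox1 had promoter regions in replicate 2 alone, the widest 8.33 kb. Krt8, a keratin of taste and Merkel cells, had a promoter region of 18.1 kb in replicate 2, while in replicate 1 a 9.51 kb region over the gene was assigned to the adjacent Krt18. Pou2f3, a factor of tuft and sweet, bitter and umami taste cells, had gene body regions in both replicates, up to 17.6 and 11.1 kb wide, and no promoter region. Merkel cell genes passed the threshold with 5 of 19 marked (26.3%, adjusted exact p = 0.0397), namely Atoh1 (10.4 and 9.93 kb), Gfi1 (29.3 and 23.3 kb), Insm1 (26.6 and 24.6 kb), Sstr1 and Sox2. Without the genes that other lists also hold, the Merkel list no longer passed (30%, adjusted exact p = 0.0941).

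Lists of genes of the epithelium itself did not pass the threshold. Of 26 basal keratinocyte genes, 3 were marked (11.5%, interval 2.45 to 30.2%, adjusted exact p = 0.575), namely Krt15 (23.5 and 20.6 kb) and the adhesion genes Itga3 (13.0 and 13.0 kb) and Dst (10.5 and 9.76 kb). Trp63, the master regulator of stratified epithelia, had no region within 1256 kb in either list, and Krt14 had none within 34.9 kb. Of 39 genes of differentiated keratinocytes, 5 were marked (12.8%, interval 4.30 to 27.4%, adjusted exact p = 0.474). They were Krt4 (19.3 and 41.8 kb) and Krt13 (23.5 and 8.03 kb), the keratins of the differentiated oral lining, Ovol1, Krt84 and Krt2. In replicate 1 the same region named Krt13 and the basal gene Krt15. In replicate 2 the Krt4 region also named Krt78 and Krt79. Housekeeping genes had 1 of 40 marked, Tubb5 (2.5%, adjusted exact p = 0.333). The olfactory receptor genes had 1 of 1110, Olfr1414 (0.0901%, adjusted exact p = 3.6e-43), below the 9.29% of other genes. With olfactory receptor genes within 100 kb counted as 1, 0 of 84 were marked (adjusted exact p = 0.0015). Each replicate alone named more genes, 12.8% and 12.4% of all protein-coding genes, and gave 15.4% and 23.1% for the basal keratinocyte list, 20.5% in both for the differentiated keratinocyte list and 12.5% and 7.5% for the housekeeping list, none past the threshold.

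Among lists of other cell types, fibroblast and mesenchyme genes had 10 of 24 marked (41.7%, adjusted exact p = 5.4e-05), including Snai1 (26.2 and 17.8 kb), Twist1 (19.1 and 24.6 kb), Pdgfra (19.4 and 20.7 kb) and Tcf21 (15.8 and 16.3 kb). Neuronal genes had 7 of 28 marked (25%, adjusted exact p = 0.0203), including Prph and Nefm (10.3 and 8.95 kb). With genes within 100 kb counted as 1, the neuronal list was at 22.2% (adjusted exact p = 0.055). Skeletal muscle genes had 4 of 22 marked (Pax3, Pax7, Tnni2 and Myod1, adjusted exact p = 0.181), glia and melanocyte genes 4 of 18 (Pax3, Foxd3, Sox10 and Kit, adjusted exact p = 0.107), endothelial genes 2 of 20 (Flt1 and Sox17, adjusted exact p = 0.728) and immune genes 2 of 28 (Kit and Csf1r, adjusted exact p = 1). Of 32 genes that encode Polycomb components, 12 were marked (37.5%, adjusted exact p = 3.3e-05), including Cbx8 (33.2 and 34.3 kb), Pcgf1 (34.8 and 15.8 kb) and Cbx6 (15.4 and 8.78 kb). Of 11 cell cycle inhibitor genes, 2 were marked (adjusted exact p = 0.333), Cdkn2a and Cdkn2b, in one region on chromosome 4 that measured 50.6 kb in replicate 1 (89265910 to 89316461) and 50.1 kb in replicate 2.

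These calls depended in part on how a gene was tied to a region. With regions within 5000 bp of either gene end, the nearest to the rule planned for lists without distances, 3 more lists passed the threshold: taste bud genes (34.4%, adjusted exact p = 0.00709), differentiated keratinocyte genes (28.2%, adjusted exact p = 0.0299) and skeletal muscle genes (31.8%, adjusted exact p = 0.0401). With 50000 bp, the Fgf, Bmp and Tgf-beta, Merkel and neuronal lists no longer passed, while the Hedgehog and skeletal muscle lists did.

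**Figure D2:**
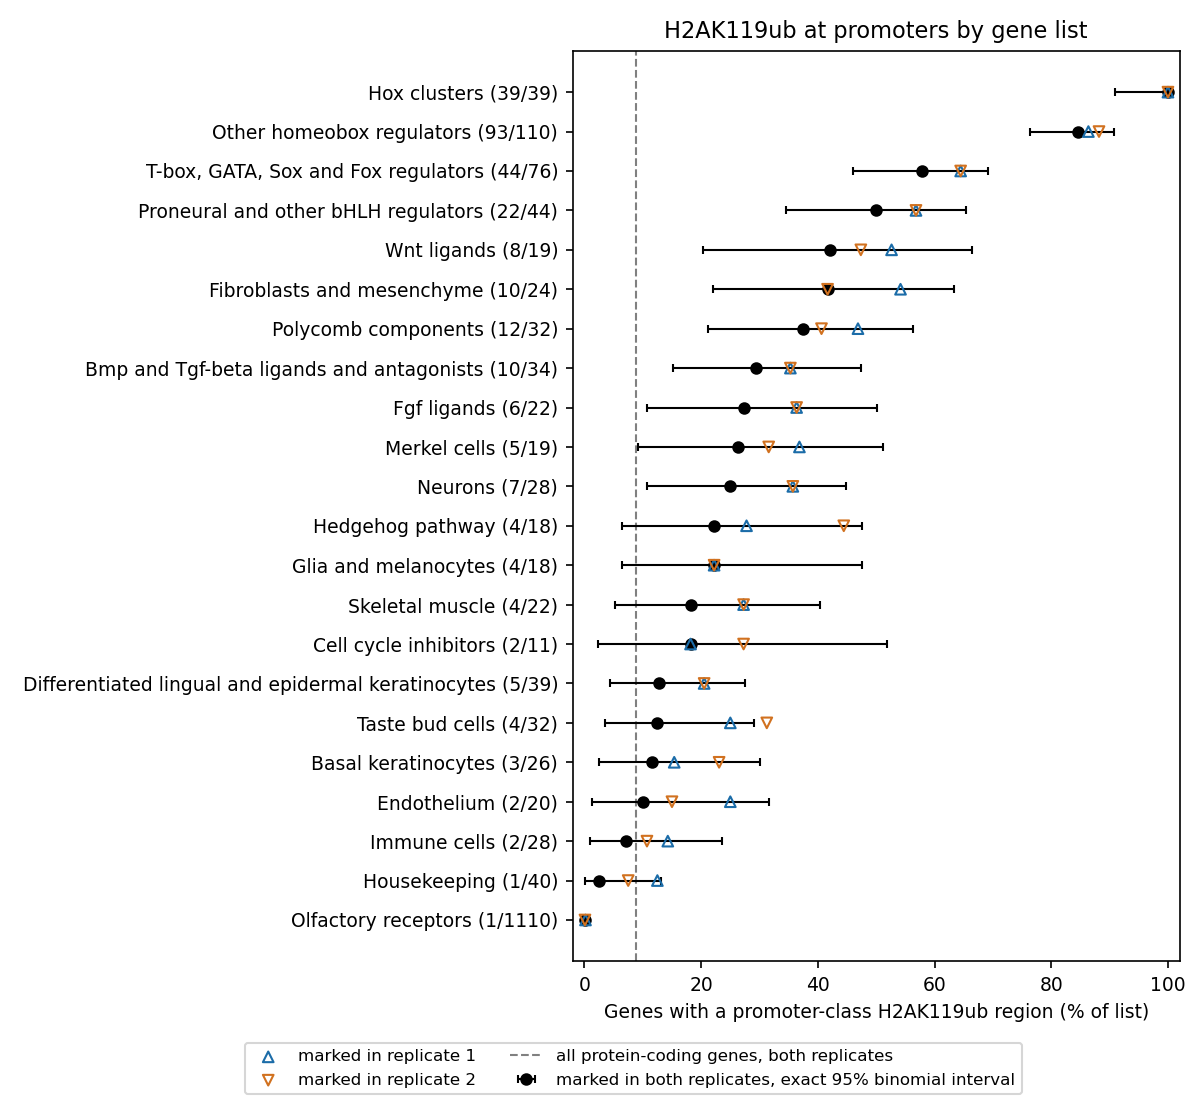
Each line is a gene list with its marked and measured genes, and the horizontal axis is the percentage of its genes with a promoter-class region. Black points show genes marked in both replicates with exact 95% binomial intervals, triangles show each replicate alone, and the dashed line marks the 8.82% of all protein-coding genes, far below the 84.5% of homeobox genes outside the Hox clusters.

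**Figure D3:**
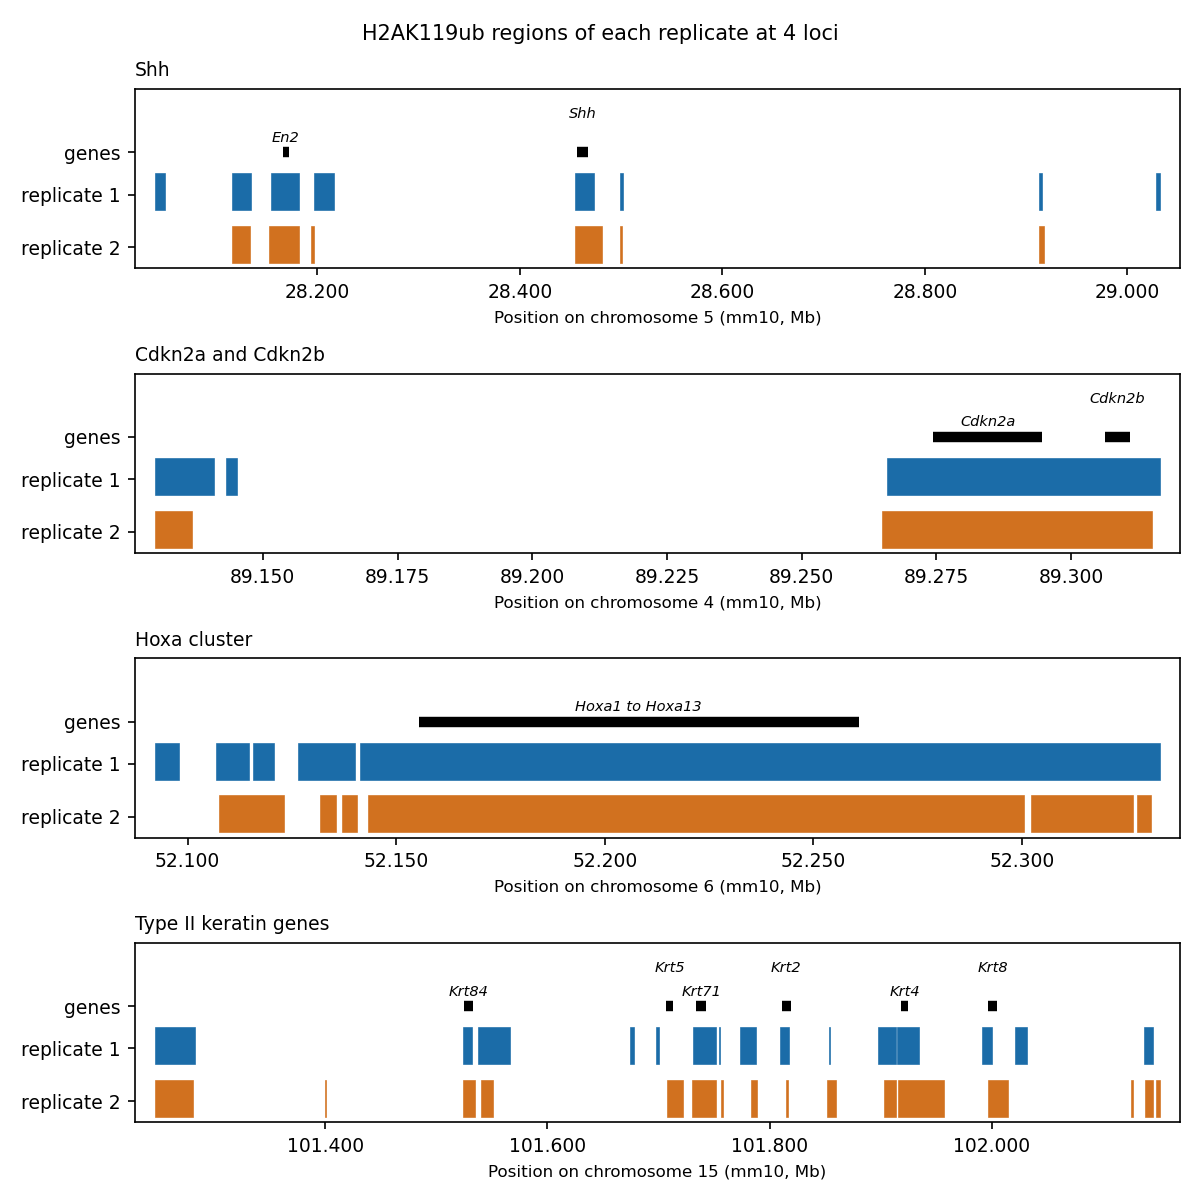
Called regions of replicate 1 (blue) and replicate 2 (orange) are drawn to scale along mm10 coordinates in Mb at 4 loci, with named genes or the span of the Hoxa genes in black. The Hoxa genes lie under 1 region in each replicate, Cdkn2a and Cdkn2b under a region of 50.6 and 50.1 kb, Shh under 19.1 and 27.0 kb, and Krt5 under a region in replicate 2 alone.

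The fourth comparison measured how much of each Hox cluster was covered. Regions covered 100% of the span from the first to the last gene of the Hoxa and of the Hoxc cluster in both replicates, and 99.5% ± 0.74 (SD, n = 2) of the Hoxd cluster. Coverage of the Hoxb cluster was 81.6% ± 3.44 (79.2% and 84.1%), with Hoxb13 in regions of its own (58.9 and 45.6 kb) apart from Hoxb1 to Hoxb9.

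The fifth comparison set the X chromosome against the autosomes. X carried 148 regions in replicate 1 (1.89% of the list, exact 95% interval 1.60 to 2.21%) and 132 in replicate 2 (1.63%, 1.37 to 1.93%), while it made up 6.53% of the gene-bearing span. Regions per Mb on X were 0.275 of the autosomal value in replicate 1 and 0.237 in replicate 2, and covered length per Mb was 0.177 and 0.160 of it. Of 966 protein-coding genes on X, 16 were marked (1.66%) against 9.16% of autosomal genes (two-sided Fisher's exact test, p = 1.3e-21). None of the 5 genes of the regulator lists on X was marked. The sex of the animals was not given in the sources used here.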

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

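For 36 results, 274 values were computed under alternatives, and 240 of them were counted as unchanged. Such values kept their side of the threshold, moved by less than their error or, for the count of marked genes (1908), ranged from 1364 to 2770. Of all values, 0 were counted as reversed. Lists that did not pass could still change direction. Without genes of other lists, glia and melanocyte genes fell from 22.2% to 0%, below the 8.83% of other genes. Within 50000 bp, housekeeping genes rose from 2.5% to 45%, above the 36.3% of other genes. With 2 replicates, leaving out 1 always keeps a location share within its SD, so those values could not move. The limit to regions above the median width, the random circular shift and the use of gene names of any location class were chosen after seeing the data. The share of shared regions stayed above random under each overlap rule tried. The location shares moved: among shared regions, promoter, gene body, distal and intergenic were 40.2%, 24.5%, 20.6% and 14.6%, and above the median width 47.0%, 22.0%, 17.1% and 13.9%. The count of marked genes was 3055 and 7846 with gene ends within 5000 and 50000 bp, 3552 in either replicate and 3301 with any location class. The ratio of regions per Mb on X to autosomes, 0.256 as the mean, was 0.162 above the median width and 0.168 by covered length. The Hox, other homeobox, T-box to Fox, bHLH, Wnt, fibroblast, Polycomb and olfactory receptor lists kept their calls under every alternative run. With gene ends within 5000 bp, taste bud (34.4%), differentiated keratinocyte (28.2%) and skeletal muscle (31.8%) lists newly passed. Within 50000 bp, Hedgehog (72.2%) and skeletal muscle (63.6%) lists newly passed, and Fgf (50%), Bmp and Tgf-beta (52.9%), Merkel (47.4%) and neuronal (53.6%) lists no longer did. With genes in either replicate, Hedgehog (50%), taste bud (43.8%) and skeletal muscle (36.4%) lists newly passed. With any location class, Hedgehog (50%) newly passed and Fgf (31.8%) no longer did. With neighbouring genes counted as 1, Fgf (21.1%) and neuronal (22.2%) lists no longer passed, nor did Merkel (30%) without genes of other lists; glia and melanocyte genes (22.2%) newly passed above the median width. Leaving out 1 replicate put Hedgehog genes at 27.8 to 44.4% and taste bud genes at 25 to 31.3%, and both passed with replicate 2 alone. The causes were not tested, apart from fewer genes or regions where an alternative removes them. A threshold on a score and a background of CpG-rich promoters were planned and not run, because the lists hold no score and no genome sequence was used. Without depth, a region missing from 1 list is not shown to lack the mark. No paired analysis was possible because there was 1 group.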

Other observations

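The test of the X chromosome was chosen after its result was seen; the other tests of explanations were set before. Beyond the fixed lists, gene families were formed by the letters before the first digit of a symbol, an addition made after seeing the data. Of 272 families with at least 10 members, 10 were marked more often than other genes and 4 less often (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the families). The higher ones included nuclear receptors named Nr (12 of 26 marked, adjusted exact p = 1.9e-05), the Prdm genes (8 of 14, adjusted exact p = 0.000165), the calcium channel genes named Cacna (6 of 14, adjusted exact p = 0.0158) and the Nkx genes (12 of 14). The lower ones were the olfactory receptors, the vomeronasal receptor genes Vmn (0 of 355), the zinc finger genes Zfp (10 of 397, adjusted exact p = 1.4e-05) and the predicted genes named Gm (22 of 1094). The families overlap the fixed lists. Among the higher ones, Hoxa, Hoxb, Nkx, Tbx, Sox, Wnt and Pou hold genes of those lists, and the olfactory receptor family is a fixed list. These families therefore repeat, at least in part, results given above. The genes named for the most regions included long ones, such as Auts2 (15 and 13 regions), Skap1 beside the Hoxb cluster (11 and 11) and Zfhx3 (7 and 8), but also the very short RNA genes Bc1 (8 and 12) and Mir5098 (9 and 7). Bc1 and Mir5098 span 0.153 and 0.081 kb in the reference, so these regions cannot all lie over the genes they name. Among gene body assignments, 20 in each replicate named a gene that the reference places on another chromosome.

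The keratin genes named Krt did not pass the threshold as a family, with 9 of 53 marked (17.0%) against 8.80% of other genes (adjusted exact p = 0.371). On chromosome 15, promoter regions lay in both replicates at Krt84 (8.13 and 11.1 kb), Krt82, Krt71 (20.6 and 21.9 kb), Krt72 (15.0 and 5.75 kb), Krt2 and Krt4. Around Shh, both replicates also had regions at En2 (28.3 and 29.6 kb) and an intergenic region on chromosome 5 at 28912382 to 28916104 in replicate 1. These loci were picked after their values were seen.

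Regulator genes were marked more often than other genes, and 2 technical explanations were tested. If CpG-rich promoters in general were called, genes of ubiquitous complexes, most of which have such promoters, would be marked as often as homeobox genes. They were marked in 12 of 454 cases (2.64%, exact 95% interval 1.37 to 4.57%), far below 84.5%, and in 6.17% and 5.07% with either replicate alone, although CpG content itself was not measured. If neighbouring genes sharing a region made the difference, it would vanish with 1 gene per cluster, yet 85.7% of homeobox genes were then marked. Every cell uses the genes of these complexes, so CpG-rich promoters that are silent in this tissue stay open as an explanation, and no biological explanation was tested.

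Broad regions over arrays of small RNA genes may arise from reads shared between near-identical copies. Of 325 tRNA, ribosomal RNA and snRNA genes with at least 4 others of their kind within 50 kb, 32.6% were covered in both replicates, against 0.688% of 1017 isolated ones, groups that differ in their make-up. Within a kind, the shares were 21.3% against 1.02% for tRNA genes (two-sided Fisher's exact test, p = 1.2e-07) and 15.8% against 0.442% for snRNA genes (Fisher's exact p = 0.000246). Genes of an array share regions and are not independent observations, so these p-values overstate the evidence. All 48 arrayed ribosomal RNA genes lay in the region on chromosome 8, and 15 tRNA genes lay in a region of 25.4 and 24.4 kb on chromosome 1. The mark itself on such arrays stays open, since a signal from the input was not analysed here.

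Regions called in 1 replicate only may lie near the calling limit. Shared regions were wider by a factor of at least 1.88 in either list, the difference that explanation needs. A wide region also overlaps another by 1 bp more easily, so part of the difference can come from the overlap rule. With an overlap of at least 50% of both regions, the factors were 1.83 in replicate 1 and 2.07 in replicate 2. Not all unshared regions were narrow: 570 of replicate 1 and 655 of replicate 2 were wider than the median shared region. Nearness to the limit is a matter of signal strength, which the lists do not hold, so widths alone could not decide it. A biological difference between the animals stays open and was not tested.

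A hypothesis was that regions outside promoters arise by spread from marked promoters. Of the shared regions outside promoters, 30.8% in replicate 1 and 31.0% in replicate 2 lay within 50 kb of a shared promoter region, against 8.85% and 8.43% after circular shifts (one-sided permutation test, p = 0.001 each, the smallest that 1000 shifts can give), which is consistent with spread for that part but also with separate elements near the same genes. A second hypothesis, that marked genes have wide gene-free flanks, was not borne out for marked genes as a whole. Their median distance to the nearest other protein-coding gene was 4.23 kb against 5.18 kb for other genes (two-sided permutation test, p = 0.0121), and without olfactory receptors 4.18 against 4.41 kb (permutation p = 0.519). The genes of the 4 regulator lists, marked or not, had a median of 15.3 kb, a difference that was not tested, and marked genes outside those lists had 3.6 kb. Another hypothesis, that basal keratinocyte genes carry regions beyond their promoters, could not be decided. Of these genes, 15.4% had a region of both replicates over the gene or within 2 kb (exact 95% interval 4.36 to 34.9%), equal to the median of 10000 length-matched random lists, whose central 95% range ended at 34.6%. A share at or below that median had been set beforehand to count against the hypothesis. The interval of the share reached past that range, however, so 26 genes could not settle it.

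Fewer genes on X do not account for the whole of its shortage of regions. X had 0.145 regions per protein-coding gene as the mean of both lists (0.153 and 0.137), while the lowest autosome, chromosome 7, had 0.254. Regions on X were also narrower, with medians of 3123 bp against 4911 bp on autosomes in replicate 1 and 2916 bp against 4254 bp in replicate 2. The number of X copies was not tested.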
